A study of Homo sapiens with 7 samples.

How the data were processed

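BrU-seq signal was analysed in 7 libraries of human RPE1 cells: 3 WT, 3 CFAP20-KO and 1 rescue. Per the labels' protocols, cells were labelled for 30 min with 2 mM bromouridine and libraries were sequenced as paired 151-bp reads. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.7a, HOMER 4.8.2, SAMtools 1.11 and R 4.0.5, with genome hg38. Their order and parameters are not given in the sources used here.

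The deposited density tables hold signal (coverage) per 200-bp bin, 100 kb to each side of transcript start sites or of OK-seq origin centres, on the transcribed strand. The authors scaled each library, and the reference of the scaling is not given in the sources used here. All values were whole multiples of 1 step per library. Because 1 fragment covers neighbouring bins, steps are not reads, so count models were not used and limma was applied to log2 values, as planned for a normalised signal. Counting intervals were not computed for the same reason. The deposited splice table holds an index per intron as a fraction from 0 to 1, for 6709 introns of 2979 genes, and 6537 introns with values in all 6 WT and CFAP20-KO libraries were used. Depth per intron is unknown. The deposited differences between index columns, which the authors made within runs (CFAP20-KO replicate 1 minus WT replicate 1, CFAP20-KO replicates 2 and 3 each minus WT replicate 3, rescue minus WT replicate 2), equalled the differences of the columns to within 3.8e-08. A number in the column names of this table was taken as a run identifier and is assumed to hold for the density tables. What this number stands for is not given.

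Transcript identifiers of the start-site windows came with no gene names. Named genes were instead measured in the origin windows. Protein-coding genes of GENCODE 44 longer than 3 kb, with no coding neighbour on the same strand within 2 kb, were kept when their body, up to 100 kb from the start, lay in a window of the same strand (at least 10 kb of it for longer bodies). This located 2083 of 14839 genes. CFAP20 was not among them and was not analysed here. Genes overlapping others on the opposite strand were kept, since the tables hold 1 strand, but imperfect strand marking could mix them. The pseudocount was the 10th percentile of non-zero values (0.0832 for genes, 0.0498 for start-site windows), and 1756 genes and 4768 of 9123 windows with a mean of at least this value were tested. Changes are on the log2(signal + pseudocount) scale, which understates changes of low genes.

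The comparison was CFAP20-KO against WT, 3 against 3 libraries, with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes, statmod 1.5.0) and Benjamini-Hochberg adjustment at 0.05. Per-library values were compared by two-sided exact permutation tests, whose smallest possible p is 0.1. Ratios used genes of at least 10 kb for start to body, 909 genes for the region past the end, and bins mostly inside annotated exons against bins away from exons for splicing. The splicing ratio was taken from bins after both the bins and the splice index had been seen per library, and the splice index was added as a result of its own. Lists of genes were tested with camera (preset correlation 0.01, and estimated) and fry. The lists reported covered cilia, the Hedgehog pathway, Mediator, RNA polymerase II elongation, R-loops, replication and its checkpoint, mitosis, immediate early, YAP and TEAD, matrix, interferon, inflammatory, stress response, cholesterol, long genes, ribosomal proteins, retinal pigment epithelium and 3 kinds of other cells. Named genes were, by a rule fixed before the data were examined, the 10 with the largest rise and fall among genes past the threshold, with groups that do not overlap and a mean signal in the upper part of the tested genes, with up to 3 passing members per list. The planned fit selected none, and 1 gene fixed by name and 1 list are not reported here. The rule was then applied to the fit with the run as a covariate, except for its part on ratios. Genes had to pass in that fit, but were ranked by their change in the planned fit.

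Replicate numbers were checked as pairs by correlating deviations from group means. For named genes the same-numbered pairs correlated at 0.83, 0.58 and 0.04, and for start-site windows at 0.59, 0.33 and 0.06, so numbers were not taken as pairs. For the start-to-body ratio (0.59, 0.24 and 0.22), the exon-to-intron ratio (0.48, 0.13 and 0.27) and the splice index (0.51, 0.21 and 0.21) they met the limit of 0.1. The pairs numbered 1 and 3 also share a run. For named genes, WT replicate 3 correlated at 0.098 and 0.039 with CFAP20-KO replicates 2 and 3 of its run. WT replicate 2 correlated at 0.65 with CFAP20-KO replicate 3 of another run. The run therefore also missed the limit of 0.1 for named genes. CFAP20-KO replicates 2 and 3 differed by 10.7 times the counting noise of the steps, and the other pairs of WT and CFAP20-KO libraries by 153 to 993 times. Fragments that cover several bins raise this value too, so it does not show that the 2 came from separate cultures. They were kept as 2 samples because the labels list them so, and a fit on their mean was added. Of the tests, only the limma fits of 3 against 3 libraries were tried on simulated data. Its noise was independent between libraries and genes, with variances drawn from limma's fitted prior. This replaced a first version that used each gene's own estimated variance, which scatters more than the true variances; with it, 2.99%, 22.4% and 72.7% of named genes changed by 0.5, 1 and 2 were recovered. For the sizes given below, the first version recovered 1.49%, 29.9% and 72.7% of start-site windows, 0%, 4.48% and 42.4% for start to body, 0%, 17.9% and 77.3% for exon to intron, and 7.46%, 10.4% and 36.4% for the splice index. Sizes for start-site windows were raised to 1, 2 and 4 after smaller ones were not recovered, and 4.48%, 43.3% and 87.9% were then recovered. The start-to-body test recovered 0%, 1.49% and 71.2% of changes of 0.5, 1 and 2, the exon-to-intron test 1.49%, 5.97% and 54.5%, and the splice index test 0%, 10.4% and 28.8% of changes of 0.1, 0.2 and 0.4.

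For the rescue, 534 named genes were matched to start-site windows by the shape of their signal (correlation above 0.9 and at least 0.1 above the next), with a median absolute log2 difference of 0.0488. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives covered the pseudocount, filter, scaling, regions, replicate block, each library left out, and the run as a covariate, the last chosen after the files were seen.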

Results

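Nascent RNA was measured by bromouridine labelling and sequencing (BrU-seq), in which RNA made during a 30-min pulse with 2 mM bromouridine is captured with an antibody and sequenced. The cells were RPE1, an immortalised human retinal pigment epithelial line, carrying an inducible Cas9. There were 3 wild-type (WT) libraries, 3 libraries of cells without CFAP20 (CFAP20-KO), a protein known from cilia, and 1 library of CFAP20-KO cells expressing CFAP20-GFP (rescue). The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Values were coverage per 200-bp bin on the transcribed strand, scaled by the authors. The smallest step of this scale, which falls as depth rises, ranged from 0.0733 in WT replicate 2 to 0.393 in CFAP20-KO replicate 1. The steps in the windows around replication origins summed to 96532606 in WT replicate 2 and to 20447648 in CFAP20-KO replicate 1. Column names of the splice table carry a number that takes 3 values, and libraries sharing it are said here to share a run. Whether it marks sequencing runs or another grouping is not stated. WT and CFAP20-KO replicate 1 shared a run, WT replicate 2 and the rescue shared another, and WT replicate 3 shared the last with CFAP20-KO replicates 2 and 3.

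The first comparison addressed whether loss of CFAP20 changed transcription of genes. CFAP20 itself was not analysed here, so the knockout could not be checked in these values. Of 1756 genes tested with limma in the planned comparison of 3 against 3 libraries, 0 were higher and 0 lower at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 147 genes, 93 of them higher in CFAP20-KO, and the smallest adjusted p was 0.12. The 3 CFAP20-KO values lay entirely above or below the 3 WT values for 310 genes (17.7%), where chance gives 10% if the 6 libraries are exchangeable. With CFAP20-KO replicates 2 and 3 averaged the share was 19.3%, where chance gives 20%. In simulated data of the same size, the test recovered 0% of genes changed by 0.5 on the log2 scale, 2.99% of those changed by 1 and 66.7% of those changed by 2. The simulated noise was independent between libraries and genes, unlike the real deviations, so these shares may not hold for the real libraries.

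A fit with the run as a covariate, added after the files had been seen, called 110 genes higher and 83 lower. WT replicate 2 shares its run only with the rescue, which was not fitted. It therefore has no weight in the changes of any fit with the run covariate, which rest on WT replicates 1 and 3. The WT means given beside these changes include it. With each library also centred on its median the split was 41 higher and 118 lower, and with CFAP20-KO replicates 2 and 3 averaged it was 73 and 57. These 2 libraries resembled each other more than any other of the 15 pairs of WT and CFAP20-KO libraries (correlation 0.997 over start-site windows, next 0.952), and 95 of the 193 calls were also made when they were averaged. The rule fixed for naming genes selected none in the planned fit and was therefore applied to the genes that passed in this added fit with the run covariate. They were still ranked by their change in the planned fit, and had to be separate from all 3 WT libraries, WT replicate 2 included. For named genes the run also missed the limit used to judge pairing by replicate number. Among the genes it selected as higher was OPTN, which encodes the autophagy receptor optineurin (chromosome 10, 13100163 to 13138308, hg38). Its signal was 2.22 in WT and 7.17 ± 1.29 (SD, n = 3) in CFAP20-KO. The run-adjusted log2 change was 1.67 (SE 0.19, limma adjusted p = 0.0298, against 0.12 in the planned fit), and the change was 1.61 and 1.72 within the 2 runs that held both groups. MMP2, a secreted matrix metalloproteinase, had 20.7 in WT and 53.6 ± 14.6 in CFAP20-KO, a run-adjusted change of 1.23 (SE 0.12; 1.30 and 1.17 within runs). The other genes selected as higher were HACD1, SPOCK1, EDIL3, MCM10, FBN1, CLMP, SH3RF2 and SH2D4A. OPTN, MCM10 and HACD1 lie in 1 block of chromosome 10 (10 to 20 Mb), where 10 of 13 tested genes were called with the run covariate or the replicate block. FBN1 encodes the matrix protein fibrillin-1 and MCM10 a replication factor, and their run-adjusted changes were 0.96 and 0.94. In the planned fit OPTN and FBN1 changed by 1.64 and 0.97, and by 1.004 and 0.615 over the first 3 kb.

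Among the genes selected as lower, LAMB1, encoding a laminin chain (chromosome 7, 107923799 to 108003161), had a signal of 9.25 ± 0.406 in WT and 3.95 ± 0.609 in CFAP20-KO (SD, n = 3). Its run-adjusted change was -1.24 (SE 0.13; -1.41 and -1.11 within runs). SPRY1 and DUSP5, both negative regulators of growth factor signalling to MAP kinases, changed by -1.22 and -1.06. The transcription factor gene BHLHE41 changed by -1.03, and S100A10 by -1.28 (-0.905 in the planned fit, and -0.496 there without WT replicate 3). The remaining genes were SYPL1, THAP5, ZNF746, ZNF805 and RHEB. LAMB1, SYPL1, THAP5, ZNF746 and RHEB, 5 of these 10, lie on chromosome 7 beyond 100 Mb. ZNF805 (chromosome 19, 57240632 to 57262728) lies in a 10-Mb block where 7 of 10 tested genes were called with the run covariate or the replicate block. The median change of that block, centred on all genes, was -0.55 and -1.12 within runs. Over the 20 genes the limma adjusted p ranged from 0.0298 to 0.0331 with the run covariate and from 0.12 to 0.596 without it. Their SEs were 0.115 to 0.186 with the run covariate, and 0.292 to 0.332 when CFAP20-KO replicates 2 and 3 were averaged. The covariate fit counts these similar libraries as independent, and averaging also leaves fewer libraries. What raised the SEs was not tested. Averaging still gave smaller limma adjusted p-values for most of the 20 genes, such as OPTN (5.4e-05), and larger ones for RHEB, SH2D4A, MCM10 and SH3RF2. With so few libraries its p-values lean on variance pooled over genes, so passing it is not a stricter check. RHEB, SH2D4A and MCM10 did not pass with the averaged replicates (adjusted p = 0.0846 and 0.0756 for the first 2, and just above 0.05 for MCM10). With centred libraries, FBN1, CLMP and SH2D4A did not pass with the run covariate (adjusted p = 0.0583, 0.0507 and 0.0686), and these and SH3RF2 did not pass with the replicate block (adjusted p from 0.0761 to 0.1004).

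**Figure D1:**
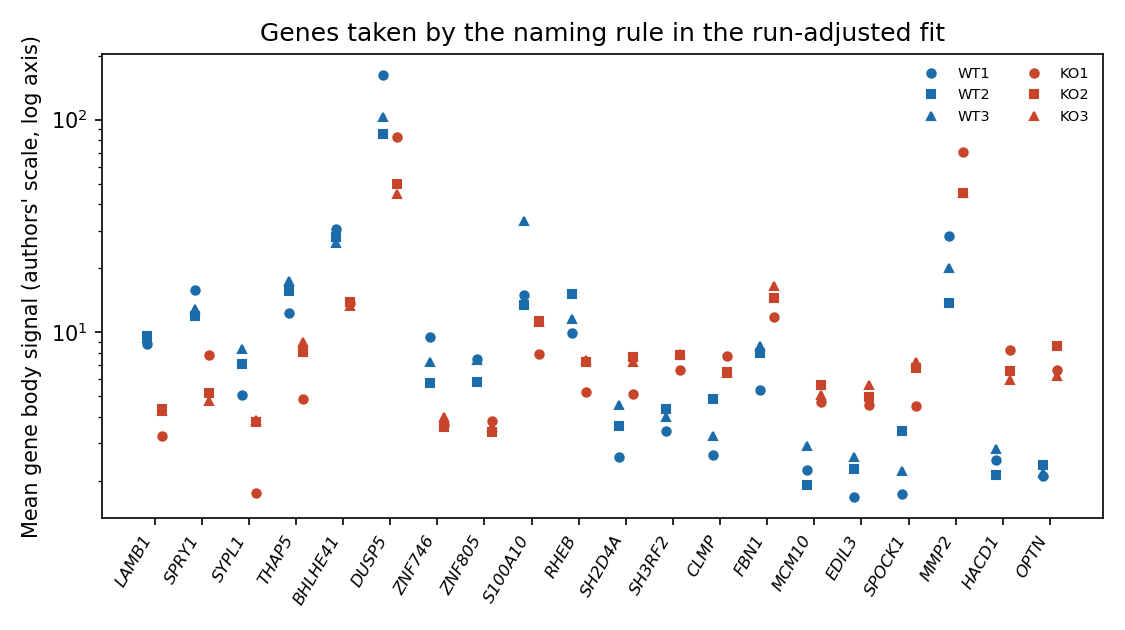
Mean gene body signal (authors' scale, log axis) of the 20 genes selected by the naming rule among those passing in the run-adjusted fit. There is 1 point per library, WT in blue and CFAP20-KO in red. The first 10 genes are lower and the last 10 higher in all 3 CFAP20-KO libraries than in all 3 WT libraries, for example LAMB1 (9.25 against 3.95 on average) and OPTN (2.22 against 7.17); the genes were selected for this separation.

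Of the gene lists fixed before the data were examined, 15 had at least 3 members with gene body signal, and none passed the camera test (smallest adjusted p = 0.171). In the planned fit 0 members of any list passed limma's test over all genes. Adjusted over the list alone, 1 long and fragile-site gene and 1 replication licensing gene passed, and 0 in the other lists. The 7 mesenchymal and matrix genes had a median log2 change of 0.59, against 0.17 for all genes, and the 7 immediate early genes -0.24 (camera adjusted p = 0.171 for both). The 6 long and fragile-site genes had a median of -0.11, the 3 interferon-stimulated genes -0.48 and the 3 ribosomal protein genes -0.38. The interferon median is that of SAMD9, which changed in opposite directions within runs (-1.46 and 0.89). With the run covariate the median of the interferon list was -0.12. Medians were 0.06 for 5 cilium assembly genes, -0.11 for 4 Hedgehog pathway genes, 0.22 for 6 Mediator genes, 0.24 for 3 elongation genes, 0.06 for 3 R-loop genes, 0.04 for 7 replication licensing genes, -0.14 for 4 mitotic genes, 0.21 for 3 stress response genes and -0.07 for 6 YAP and TEAD targets. In the run-adjusted fit, members that passed limma's test were MAGI1 (1.16, against 0.59 in the planned fit) and IMMP2L (-1.07, -1.02) among the long genes, EVC2 (-1.12, -0.73) in the Hedgehog list, NR4A1 (-0.64, -0.24) among immediate early genes, CENPA (-0.64, -0.15) among mitotic genes, RPS14 (-0.65, -0.38), the retinal pigment epithelium marker RLBP1 (-1.21, -1.11), and MCM10 and FBN1 as given above. With the averaged replicates NR4A1, CENPA and RPS14 did not pass (adjusted p = 0.285, 0.183 and 0.255), and NR4A1 and CENPA changed sign in the planned fit when 1 library was left out or over the first 3 kb. Of markers of other cell types, the epithelial gene ELF3 changed by -0.96 with the run covariate (adjusted p = 0.0484, and 0.0508 with the averaged replicates; -0.48 in the planned fit), and the neuronal genes MAP2 (-0.87, adjusted p = 0.0513) and SYT1 (0.09) did not pass. No haematopoietic marker and 2 cholesterol genes and 2 inflammatory genes were among the genes tested, and none of these passed.

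The next comparison concerned where nascent RNA lay along genes. The median log2 ratio of signal in the first 2 kb to the rest of the gene body was 1.47 ± 0.511 (SD, n = 3) in WT and 1.23 ± 0.355 in CFAP20-KO, a difference of -0.24 (exact permutation p = 0.7, where 3 against 3 cannot give less than 0.1). It was lower in CFAP20-KO within both runs, by values of -0.26 and -0.59, but WT replicate 2 had the lowest ratio of the 6 libraries (0.90). Without that library the difference was -0.53, and without WT replicate 1 it was -0.033. In limma, 0 of 1592 genes had a changed ratio, 5 with the replicate number as a block, and 297 with the run covariate, of which 286 were lower. After centring each library the run covariate gave 12 genes, 6 in each direction.

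**Figure D2:**
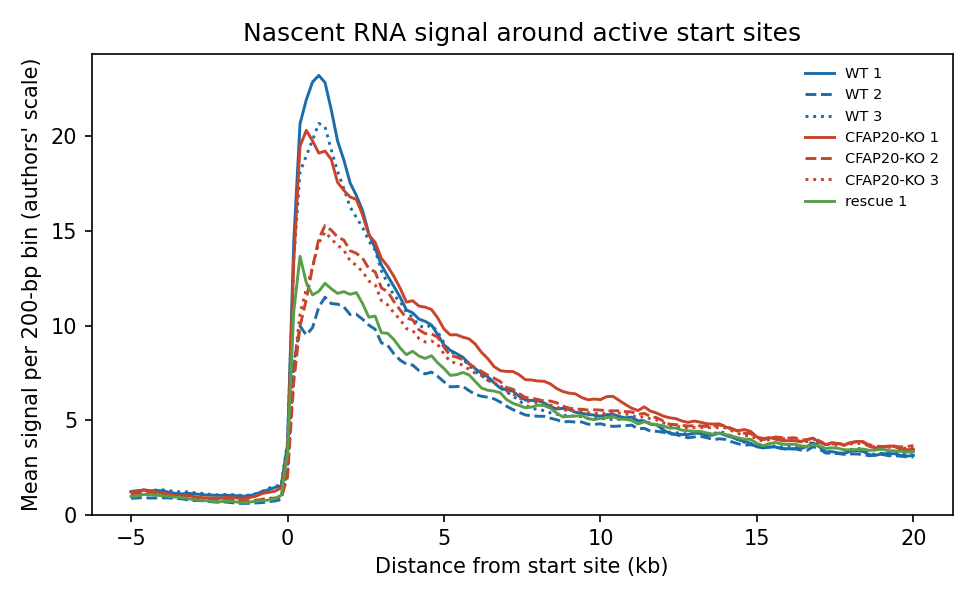
Mean signal per 200-bp bin (authors' scale) against distance from the start site (kb), over 3367 active start-site windows, with 1 line per library (WT blue, CFAP20-KO red, rescue green). About 1 kb after the start site the WT lines lie on both sides of the CFAP20-KO lines, with WT replicate 2 lowest and WT replicate 1 highest.

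For elongation into long genes, the share of signal beyond 50 kb within the first 100 kb was 39.4% ± 3.01 in WT and 38.1% ± 5.68 in CFAP20-KO (SD, n = 3; 20 genes; exact permutation p = 0.8). The direction differed between runs, at -4.95 and 2.34 percentage points. Genes of at least 100 kb had a median signal 2.43 log2 units below that of genes of 3 to 10 kb in WT, as a difference of -2.43 ± 0.816, and -2.03 ± 0.451 in CFAP20-KO (exact permutation p = 0.5). The CFAP20-KO minus WT value was 0.40, with 0.43 and 1.04 within runs. It was 0.87 without WT replicate 2, 0.12 without WT replicate 1, 0.040 with no filter on signal, and 0.078 for genes of at least 60 kb against 3 to 30 kb. Past gene ends, the log2 ratio to the last 5 kb was -1.65 in WT and -1.58 in CFAP20-KO (exact permutation p = 0.8). Upstream of genes, where little signal is present, the ratio to the gene body was -3.95 ± 0.263 in WT and -4.29 ± 0.234 in CFAP20-KO (difference -0.35, exact permutation p = 0.2), and -0.23 and -0.63 within runs. The median log2 signal of all genes was 1.68 ± 0.108 in WT and 1.88 ± 0.157 in CFAP20-KO (difference 0.19, exact permutation p = 0.3). Adjusted over the 11 values of this kind, the p-values were 0.88 or more.

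For splicing, the log2 ratio of exonic to intronic bins was 0.21 ± 0.288 in WT and 0.03 ± 0.432 in CFAP20-KO (SD, n = 3; exact permutation p = 0.7), and -0.40 and 0.09 within runs. In limma 0 of 1159 genes changed. The deposited splice table gave an index per intron, between 0 and 1, whose definition and depth are not given. Its median was 0.629 ± 0.0774 in WT and 0.637 ± 0.103 in CFAP20-KO (exact permutation p = 0.9; -0.0243 and 0.046 within runs). Of 6537 introns 0 passed limma's test. At an unadjusted p under 0.05 there were 373, the smallest adjusted p was 0.833, and groups did not overlap for 723 introns (11.1%, against 10% by chance for 6 exchangeable libraries, and 15.4% against 20% with CFAP20-KO replicates 2 and 3 averaged). With the replicate block and centred libraries 17 introns were higher and 17 lower. Among 16 lists, the 31 ribosomal protein genes had a median index change of 0.0301, with a camera adjusted p of 0.0498, an adjusted p = 0.883 with an estimated correlation, and a fry adjusted p of 0.923. With each library centred these were 0.0201, 0.340 and 0.0060. No other list passed in the first of these fits, with camera adjusted p-values of 0.139 or more.

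The series also asked how transcription relates to replication origins mapped by OK-seq, which sequences Okazaki fragments. Signal within 10 kb of 4767 origin centres relative to flanks was 1.18 ± 0.268 in WT and 1.04 ± 0.197 in CFAP20-KO (SD, n = 3; exact permutation p = 0.6), and lower by values of -0.12 and -0.36 within runs. Signal after the centres relative to signal before them, in the direction of the nearest gene, was 0.71 ± 0.126 and 0.81 ± 0.0315 on the log2 scale (exact permutation p = 0.4). The 1070 genes starting within 25 kb of an origin differed from 686 other genes by -0.35 ± 0.205 in WT and -0.31 ± 0.0821 in CFAP20-KO (exact permutation p = 0.8). All of these genes were measured in the windows around origins, so the 686 others are not genes away from origins. Whether these 686 genes lay near further origins was not tested. The comparison therefore cannot set genes near origins against genes far from any.

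Start-site windows, whose transcript identifiers were not paired with gene names, gave 10 windows higher and 4 lower in CFAP20-KO among 4768 tested with limma. Of the higher windows 8 were listed at 0 in all 3 WT libraries, and 2 of the lower ones at 0 in all 3 CFAP20-KO libraries. For uc002qrh.3 the first 3 kb had 5.15 ± 3.57 in CFAP20-KO and was listed at 0 in WT (adjusted p = 0.00631). For uc002nqd.2 the values were 12.3 ± 8.48 and 0.495 ± 0.434 (adjusted p = 0.0472). Conversely uc002qpg.4 had 5.46 ± 2.14 in WT and was listed at 0 in CFAP20-KO (adjusted p = 0.00273), and uc003ewj.4 had 2.51 ± 0.0357 in WT and 0.0929 ± 0.0306 in CFAP20-KO (adjusted p = 0.00811). Leaving out any 1 library left 1 to 6 higher and 1 to 3 lower windows, and the run covariate gave 118 and 668. In the rescue library, which has no replicate, 1 of the 14 windows (7.14%) was nearer to the WT mean than to the CFAP20-KO mean. All others were nearer to the CFAP20-KO mean. Simulations without rescue gave 0.171% on average. They used the spread within groups of windows selected on these same libraries, and no run effect, so a share near 0 was fixed in advance. The run of the rescue held no CFAP20-KO library, so this comparison does not show rescue. All 8 windows at 0 in WT had signal in the rescue, including 4.44 for uc002qrh.3, and uc002qpg.4 was listed at 0 there.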

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

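Tests with the run as a covariate, with averaged replicates, of start-site windows, of the splice index and of signal after origin centres were chosen after the data were seen. The planned count of 0 genes higher and 0 lower held under other pseudocounts, filters, regions and scalings and without any 1 library (0 to 0). With the replicate block it became 97 higher and 69 lower, and with block and centring 30 and 74. WT replicate 2 correlated more with CFAP20-KO replicate 3 than with replicate 2, so the numbers do not pair these libraries best. The run covariate gave 110 and 83, with centring 41 and 118, and with averaged replicates 73 and 57. Of the 193 run-adjusted calls 93 were among the 166 calls with the block. The cause was not tested. Genes with a changed start-to-body ratio went from 0 to 5 (block), 297 (run) and 12 (run with centring), and without any 1 library were 0. Genes with a changed exon-to-intron ratio were 0 to 1 without 1 library, the 1 without CFAP20-KO replicate 1, and 0 with the block.

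Start-site windows (10 higher, 4 lower) became 2 and 2 at an adjusted p of 0.01, 16 and 10 with plain empirical Bayes, 17 and 13 with the block, 118 and 668 with the run, 18 and 12 centred, 130 and 198 with block and centring, and 263 and 455 with run and centring. Without 1 library they were 1 to 6 and 1 to 3. Introns with a changed splice index (0 and 0) were 17 and 17 with block and centring and 36 and 24 with run and centring, and 0 with the block or without any 1 library. The splice index lists passing camera (1, ribosomal proteins) went to 0 with an estimated correlation or with fry, and stayed at 1 centred, with the block and with the run. Fry gave ribosomal proteins when centred (adjusted p = 0.0060) and elongation genes with the block (0.0140), and 0 lists with the run. Its version for changes in both directions gave 0 of 16 lists in the planned fit, 1 centred, 3 with the block (among them R-loop genes, 0.00129) and 7 with the run. Gene body lists stayed at 0 by camera and fry, also centred, with the block and with the run. Fry for both directions gave 1 of 15 centred, 0 with the block and 10 with the run. The rescue share was 7.14% (1 of 14 windows), 25% at an adjusted p of 0.01 (1 of 4) and 13.3% centred (4 of 30). The cause was not tested.

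Per-library differences passed no threshold under any setting, which a design with a smallest p of 0.1 could not show. The block keeps the mean difference, for example 0.19 for all genes and -0.24 for the start-to-body ratio, and changed no call among them. Without 1 library the ranges were 0.13 to 0.28 for all genes, -0.53 to -0.03 for the start-to-body ratio, 0.12 to 0.87 for gene length (0.12 without WT replicate 1; 0.040 with no filter and 0.078 for the other length classes), -0.50 to -0.26 upstream, -0.29 to -0.04 at origin centres and 0.04 to 0.16 after against before them. The sign changed for the share beyond 50 kb (-3.48 to 1.91; 0.302 without WT replicate 2 and 1.91 without CFAP20-KO replicate 1), downstream (-0.0784 to 0.15; -0.0784 without CFAP20-KO replicate 1), exons (-0.32 to 0.0696; 0.0696 without CFAP20-KO replicate 1), genes near origins (-0.0345 to 0.15; -0.0345 without WT replicate 1, -0.0140 without WT replicate 3, -0.0030 without CFAP20-KO replicate 3, and -0.0430 within 50 kb) and the splice index (-0.0347 to 0.0673; -0.0347 without WT replicate 1, -0.0266 and -0.0163 without CFAP20-KO replicates 2 and 3). The cause was not tested.

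For the 28 named genes, 435 of 554 alternatives kept direction and side, 114 passed only in the block or run fits, and 5 reversed. NR4A1 (-0.675 to 0.01001 without 1 library) reversed to 0.01001 without WT replicate 1 and 0.41 over the first 3 kb, and CENPA (-0.555 to 0.173 without 1 library) to 0.173 without WT replicate 3, 0.0129 without CFAP20-KO replicate 1 and 0.0307 over the first 3 kb. Without 1 library, planned values also moved over 1.5 times for S100A10 (-0.905 to -0.496 without WT replicate 3), MAGI1 (0.590 to 0.249 without WT replicate 3, 0.393 without CFAP20-KO replicate 1 and 1.08 without WT replicate 2), RPS14 (-0.379 to -0.208 without WT replicate 1 and -0.668 without WT replicate 2) and ELF3 (-0.483 to -0.011 without WT replicate 1, -0.257 without CFAP20-KO replicate 2 and -1.08 without WT replicate 2, and -0.73 without CFAP20-KO replicate 1). The count model for whole reads, other pseudocounts for the share beyond 50 kb and for origins, and an unfiltered version for origins were not run, since the values are not counts or use no pseudocount or filter.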

Other observations

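The tests of chance splits, of runs as a source of the block pattern, and of chromosome 7 were chosen after the results were seen. Those of copy number and of rescue in the blocks were written after the pattern had been noticed among the top genes. The slope for the rescue was recomputed once, after a first version that used WT replicate 2 on both sides.

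Neighbouring genes changed together. Differences in the tests of blocks and of chromosome 7 were centred on the median over genes. The bootstrap intervals of both tests resampled single genes as if independent, so they are likely too narrow. In 10-Mb blocks with at least 5 tested genes (173 blocks), the share of the variance of change lying between blocks was 0.3002 for CFAP20-KO minus WT in the run of replicate 1 and 0.3122 in the run of WT replicate 3, against 0.118 with shuffled genes (permutation p = 0.0001, the smallest that 10000 shuffles can give). The same share was 0.3225 for WT replicate 3 minus WT replicate 1, which lie in different runs, so a share of this size is not specific to the knockout. Whether the same blocks were involved was not tested. In 35 blocks chosen on 1 run, the signed median change in the other run was 0.254 over all 267 genes (95% bootstrap interval 0.198 to 0.347), between the bounds set for a difference between runs (under 0.1) and against it (over 0.3). A DNA copy number difference may also produce blocks, but genes called in neither the run-adjusted nor the block fit had a median of 0.0902 (-0.00713 to 0.158, 179 genes), a test that leaves out called genes and decides nothing. If the rescue construct restored these genes, its slope on the knockout change should be under 0.5; it was 0.698 (0.544 to 0.874, 81 matched genes), but 1 rescue library excludes nothing, so these explanations cannot be told apart.

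Chromosome 7 beyond 100 Mb was singled out after its values were seen. Of its 37 tested genes 34 were lower in CFAP20-KO in both runs (median -0.96 and -0.86; without centring 32, -0.91 and -0.65), 18 were called lower in the run-adjusted fit, and the median between WT replicates 3 and 1 was 0.10. Across the genome 6 blocks had medians lower by over 0.5 in both runs, 3 of them here, and 2 blocks were higher. A candidate explanation is a DNA copy number difference between the cell populations: the 14 genes of the region called in neither fit had a median of -0.57 in the run of WT replicate 3 (-0.701 to -0.294), under the limit of -0.3 set for this explanation, but the interval reached past it, and region and limit were chosen with the values in view. In 13 matched genes the rescue minus WT replicate 2 was -0.84, beside -1.03 for the knockout; DNA was not measured, and a biological effect of CFAP20 on this region stays open.

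The 6 libraries can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. For named genes the real split gave 0 and the highest of the 9 others 0, so all 10 gave as many. For start-site windows the real split gave 14 and the highest of the others 0, so only the real 1 of the 10 gave as many. For the exon-to-intron ratio and the splice index all 10 splits gave 0. For the start-to-body ratio the real split gave 0 and WT replicates 1 and 3 with CFAP20-KO replicate 1 against the rest gave 828, which points to a structure of the samples other than genotype; that split does not follow the runs. In the origin windows, where this ratio was measured, it parts the 3 libraries with the fewest steps (20447648 to 42598739) from the 3 with the most (44662858 to 96532606). In the start-site windows it does not, with 60600387 steps in WT replicate 3 and 57767509 in CFAP20-KO replicate 3. Depth was not separated from this split.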
